A study of Mus musculus with 8 samples.

How the data were processed

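RNA sequencing libraries from 2 sorted populations of mouse liver duct cells, ST14high and ST14low, were analysed, with 4 samples in each and 8 in all. Groups and replicate numbers were taken from the labels. Per the labels' protocols, freshly sorted cells were put into TRIzol and libraries were made with an Illumina TruSeq kit. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 1.0.0 and the mouse genome build mm9 were used, with no role stated for each. The program that counted reads, the annotation release and the strand setting are not given in the sources used here. Per the file headers, the deposited files give for each RefSeq transcript its position, its gene symbol, a raw read count and an RPKM value. The count values are whole numbers that the authors deposited without normalization. The RPKM values, which the authors deposited beside the counts, are scaled by transcript length and library size; they were used only to check the relative depth of the libraries and entered no test.

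The deposited tables held 26005 transcripts of 20377 gene symbols. Transcripts of 1 gene each count the reads they share, so sums over transcripts would count reads repeatedly. For the 3507 symbols with several transcripts the transcript with the most reads over all libraries was kept, including 260 symbols with several loci. Reads shared between near-identical genes, overlapping genes or opposite strands could not be separated in these counts. The totals per library are given with the results; they ranged from 6398307 in ST14low replicate 3 to 42769988 in ST14high replicate 3. Over the 28 pairs of libraries the chi-square per degree of freedom was 18.0 to 355 and Spearman's rho across genes 0.887 to 0.985, so no pair differed by as little as counting noise.

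Differences between the populations were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with TMM factors, on genes kept by filterByExpr, with the population as the only term. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The common biological coefficient of variation was 38.4%. Fold changes are ST14high over ST14low on the log2 scale with SE, and intervals are at 95%. CPM were computed on library sizes scaled by the TMM factors. Single genes and list means were also tested by exact two-sided permutation over the 70 arrangements of the 8 libraries, for which the smallest possible p is 0.0286. DESeq2 1.42.0 (Wald test) and limma 3.58.1 (voom with quality weights) served as other tools. Gene lists were tested with limma's camera on voom values at a preset correlation of 0.01 between genes, with camera at an estimated correlation and fry beside it, adjusted over the 27 lists. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

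The design, the other settings, the 27 gene lists and the rule for named genes were fixed before the data were examined. The rule named St14, Dpp4, Ptprc, Pecam1 and Itgam; the 12 higher and 12 lower genes of largest fold change among those past the adjusted threshold with a mean of at least 10 CPM and populations that did not overlap, of which there were 0; of each list up to 4 members past the threshold or, where fewer than 2 passed, the 2 of highest mean expression; and Lgr5, Sox9, Krt19, Epcam and Spp1. The result of 1 further gene of the rule is not reported here. Other genes are named as chosen after their values were seen. The lists were biliary epithelium, bile secretion and ion transport, apical junctions and polarity, the matriptase system, Wnt and Lgr5 stem cell genes, the Notch pathway, YAP targets, the cell cycle, the primary cilium, mucins and trefoil factors, immediate early and stress response, NF-kB targets and chemokines, the interferon response, MHC class II, the extracellular matrix, integrins and focal adhesion, epithelial growth factor signals, cholesterol and lipid synthesis, oxidative phosphorylation, the cytosolic ribosome, glycolysis and hypoxia response, hepatocytes, mesenchymal cells (stellate cells, fibroblasts and mesothelium), endothelium, macrophages and dendritic cells, lymphocytes, and erythroid cells, neutrophils and platelets.

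Other settings fixed at that time were DESeq2's size factors or upper-quartile factors in place of TMM, no low-count filter or a filter of 5 CPM in at least 4 libraries, DESeq2, limma's voom, edgeR's test against a 1.5-fold change, the replicate number as a block and leaving out each library in turn. Chosen after seeing the data were the longest transcript per gene, sums over separate loci, robust dispersion, leaving out ST14high replicate 1 and ST14low replicate 2 together, DESeq2 without each library, the overlap of DESeq2's calls with the lists by Fisher's exact test, the exact test of list means and counts at an unadjusted p under 0.05. The procedure was tested on simulated data for ST14high against ST14low, drawn from the libraries' means and sizes in 3 runs of 13563 genes. It recovered 30.4% of genes changed 2-fold and 71.1% of genes changed 4-fold, with 13 false calls in all. The list test was run on 1 further simulated set with 1 list shifted, and 0 other lists were called. Genes were drawn independently in all runs, so this cannot show how often camera falsely calls lists of correlated genes.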

Results

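RNA sequencing compared 2 populations of bile duct cells sorted from the livers of C57BL/6 mice. The sort started from liver cells other than hepatocytes. It kept cells that bound MIC1-1C3, an antibody that marks duct cells, that lacked CD26 on their surface and that were not blood cells. These were divided by their level of ST14 (matriptase, a membrane-anchored serine protease of epithelial cells) into ST14high and ST14low. Each population had 4 libraries, replicates 1 to 4, from RNA of freshly sorted cells. With 1 transcript kept per gene, the ST14high libraries held 17418202, 24149337, 42769988 and 33014559 counts. The ST14low libraries held 23321501, 19878910, 6398307 and 31011678 counts. The labels do not say whether the samples came from separate animals, so all p-values measure only the spread between these samples, which may be technical. ST14high replicate 1 stood apart from the other 7 libraries on the first principal component of log2 CPM, at -107 where the others lay between -11.5 and 55.5. That component held 34.3% of the variance and the second 26.3%. On the second, ST14high libraries lay between 6.22 and 64.3 and ST14low libraries between -55.3 and -18.5. Pancreatic acinar genes, listed after some of their values were seen, summed to 12210 CPM in ST14high replicate 1. They summed to 1803 CPM in ST14high replicate 2 and to at most 136.7 CPM in the other libraries.

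The comparison asks which genes distinguish duct cells with high surface ST14 from those with low surface ST14. Duct cell genes lay at similar levels in both populations, and the St14 transcript was not higher in ST14high. Of the gene lists, 3 of other cell types had the medians farthest from 0 when all libraries were kept. Genes listed together for stellate cells, fibroblasts and mesothelium (the cell layer that covers the liver) lay higher in ST14high, with a median log2 fold change of 1.79 over 24 genes. In subsets chosen after the result was seen, the median was 3.33 for mesothelial members and 2.33 for fibroblast and muscle members. Reln and Rgs5 lay below 0, at -0.075 and -0.47. Genes of macrophages and dendritic cells lay lower, with a median of -1.86 over 18 genes, as did genes of lymphocytes, with a median of -1.47 over 15 genes. The lymphocyte genes had low counts, with a mean log2 CPM of -0.77 in ST14high and 1.17 in ST14low, so their fold changes rest on few reads. Without ST14high replicate 1 the median of stellate cell, fibroblast and mesothelium genes was 0.87. The endothelial median, at -1.62, was then farther from 0. No single gene passed edgeR's test over all genes, and the list calls at a preset correlation did not hold with an estimated one.

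St14 was measured at 305 ± 32.6 CPM (library-size scaled counts; mean ± SD, n = 4) in ST14high and 329.9 ± 49.0 CPM in ST14low. Its log2 fold change was -0.11 (SE 0.15), with a 95% interval from -0.44 to 0.21 that excludes a 1.5-fold rise. The adjusted p was 0.809 in edgeR and the exact permutation p was 0.457. The transcript counted for St14 spans positions 30896175 to 30939384 of chromosome 9 in the mouse build mm9 and held 63849 counts over the 8 libraries. Dpp4, which encodes the CD26 protein that the sort selected against, was at 159 ± 17.0 CPM in ST14high and 138 ± 33.4 CPM in ST14low (adjusted p = 0.714). Ptprc, the gene of the blood cell antigen CD45, was at 3.69 ± 3.37 CPM in ST14high and 9.55 ± 5.76 CPM in ST14low (adjusted p = 0.696). Itgam, which encodes the myeloid integrin CD11b, was at 1.04 ± 1.73 CPM in ST14high and 0.953 ± 0.448 CPM in ST14low (adjusted p = 0.985; log2 fold change 0.11, and -2.41 without ST14high replicate 1), and Pecam1, an endothelial gene, was at 25.8 ± 34.3 CPM in ST14high and 30.7 ± 20.6 CPM in ST14low (adjusted p = 0.956). Pecam1 was at 76.5 CPM in ST14high replicate 1, and its log2 fold change was -0.25, -1.78 without that library and 0.14 without ST14high replicate 3.

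**Figure D1:**
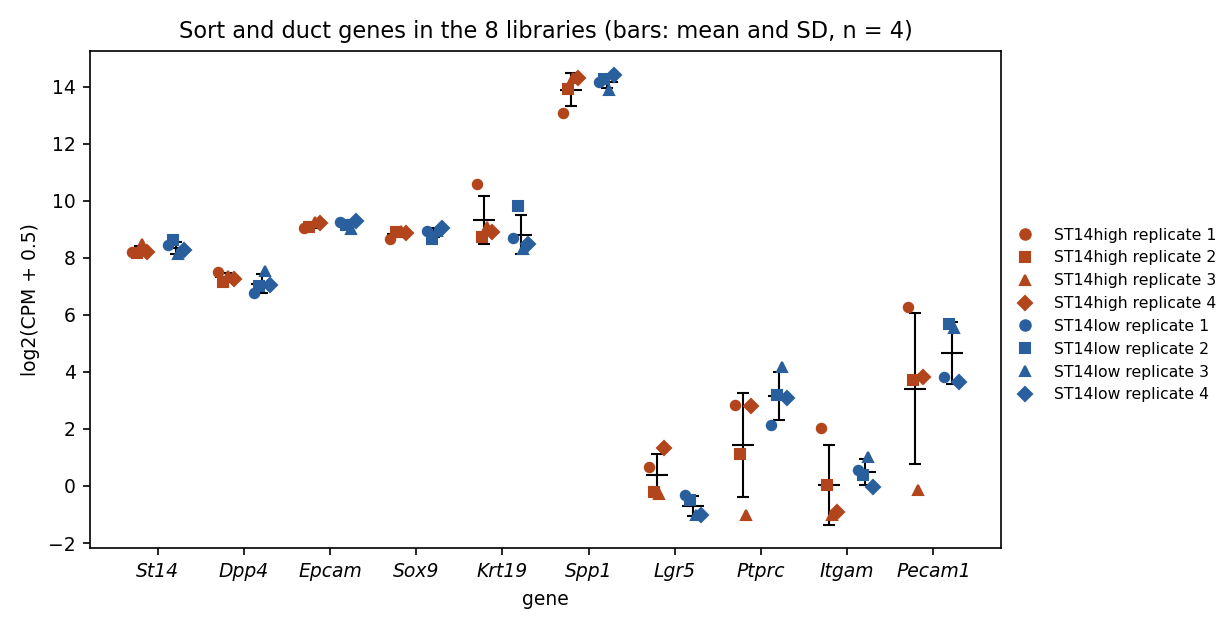
The vertical axis shows log2(CPM + 0.5) of genes of the sort and of duct cells, named on the horizontal axis, in the 8 libraries; symbols mark the replicates, colours the populations, and bars the mean and SD of 4 libraries. St14, Epcam and Sox9 lie at similar levels in both populations, and Ptprc and Pecam1 spread widely, down to 0 and 0.401 CPM in ST14high replicate 3.

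Both populations carried a duct cell profile. Epcam, an epithelial adhesion molecule, was at 571 ± 41.9 CPM in ST14high and 582 ± 54.8 CPM in ST14low. Sox9, a transcription factor of duct cells, was at 461 ± 38.2 and 477 ± 52.7 CPM. Their log2 fold changes were -0.03 (SE 0.13) and -0.05 (SE 0.13). Spp1 (osteopontin) was at 16000 ± 5374 CPM in ST14high and 18610 ± 2761 CPM in ST14low, and Clu (clusterin) at 22700 ± 6031 and 23150 ± 4738 CPM. The duct keratin Krt19 was at 740.2 ± 523 CPM in ST14high and 493 ± 268 CPM in ST14low, with 1522 CPM in ST14high replicate 1; its log2 fold change was 0.59, and -0.04 without that library. Over the 26 genes of the biliary epithelium list the median log2 fold change was -0.02, with 11 genes higher and 15 lower in ST14high (camera adjusted p = 0.505), and without ST14low replicate 2 the median was 0.05. Lgr5, a receptor that marks stem cells of several epithelia, fell under the low-count filter, at 0.938 ± 0.780 CPM in ST14high and 0.126 ± 0.150 CPM in ST14low on 118 counts in all. Its CPM was higher in all 4 ST14high libraries than in any ST14low library (exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). The gap was small, from 0.298 CPM in ST14low replicate 1 to 0.331 CPM in ST14high replicate 3. ST14high replicate 4 was highest, at 1.99 CPM.

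In edgeR's quasi-likelihood test, 0 of 13749 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.192. At an unadjusted p under 0.05 there were 1315 genes, 947 higher and 368 lower in ST14high, where chance gives 687 on average. Counts vary widely around that average, since other divisions of the 8 libraries into 4 and 4 gave 163 to 1246 genes. DESeq2's Wald test on the same counts called 234 of the 13580 genes to which it gave an adjusted p, 220 higher and 14 lower. Genes without one could not be called. Limma's voom test with quality weights called 0. All 234 genes called by DESeq2 had an unadjusted p under 0.05 in edgeR, and in 199 of them the populations did not overlap. Over all genes tested, the 4 libraries of 1 population lay above all 4 of the other in 563 genes higher and 320 genes lower in ST14high, 6.42% of the genes where chance gives 2.86%. Without ST14high replicate 1, DESeq2 called 283 genes, 201 higher and 82 lower, of which 152 were among the 234. Without ST14high replicate 3 it called 398 higher and 23 lower, and 158 higher and 3 lower without ST14low replicate 1.

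**Figure D2:**
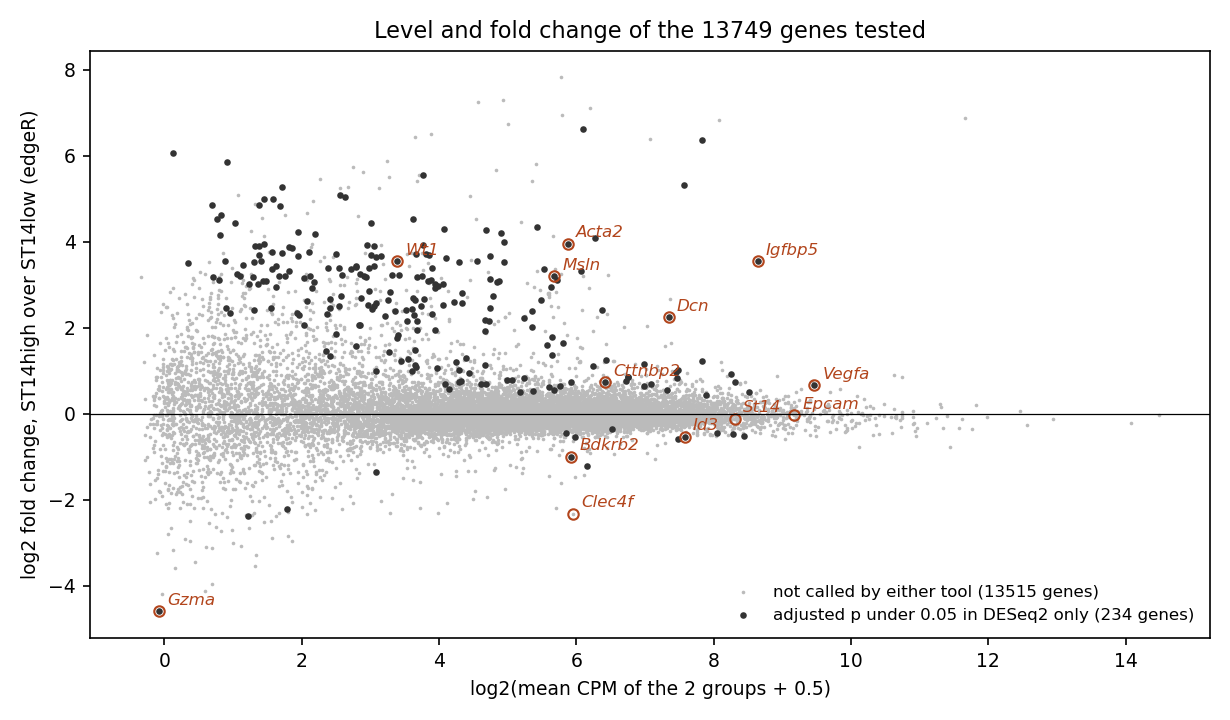
Each point is 1 of 13749 genes, with the log2 of the mean CPM of both populations plus 0.5 on the horizontal axis and edgeR's log2 fold change of ST14high over ST14low on the vertical axis; dark points are the 234 genes called by DESeq2 and circles mark genes named in the text. Of the dark points 220 lie above 0, among them Msln at 3.20, Wt1 at 3.56 and Dcn at 2.25, while St14 (-0.11) and Epcam (-0.03) lie near 0.

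Of 25 genes listed for stellate cells, fibroblasts and mesothelium, 24 were tested, and 22 had a fold change above 0 in ST14high. In edgeR 0 passed over all genes, 12 passed when adjusted over the list alone and 15 had an unadjusted p under 0.05. Of the 21 members to which DESeq2 gave an adjusted p, it called 8, all higher (Acta2, Dcn, Des, Ecm1, Msln, Upk1b, Upk3b and Wt1), where 0.362 would be expected by chance (Fisher's exact test over the 27 lists, adjusted p = 3.12e-08). Fisher's test, here and below, takes genes as independent, and its p-values are too small where genes vary together. The estimated correlation between genes of this list was 0.556. The 2 members of highest mean over both populations did not share the difference. Gpm6a, a membrane glycoprotein, was at 202 ± 33.7 CPM in ST14high and 178 ± 34.4 CPM in ST14low, and Rgs5, a pericyte gene, at 182 ± 55.6 and 252 ± 86.7 CPM. The following members, like the genes named for DESeq2's calls, were chosen after their values were seen. Msln (mesothelin; chromosome 17, 25885558 to 25891272) was at 91.0 ± 86.6 CPM in ST14high and 10.1 ± 5.06 CPM in ST14low, a log2 fold change of 3.20 (SE 0.61, adjusted p = 0.192). Wt1, a transcription factor of mesothelium (chromosome 2, 104966686 to 105013771), was at 18.5 ± 16.3 and 1.59 ± 0.586 CPM, a log2 fold change of 3.56 (SE 0.65). Dcn (decorin, a matrix proteoglycan; chromosome 10, 96942134 to 96980796) was at 268 ± 199 and 56.4 ± 15.1 CPM, a log2 fold change of 2.25 (SE 0.44). In these 3 genes every ST14high library exceeded every ST14low library, and ST14high replicate 1 was highest, at 220.4, 41.7 and 565 CPM. Camera called the list at a preset correlation of 0.01 (adjusted p = 7.16e-06) and not with one estimated from the data (adjusted p = 0.957 with an estimated correlation). Its mean log2 CPM separated the populations (exact permutation p = 0.0286, adjusted p = 0.386 over the 27 lists). The value was highest in ST14high replicate 1, and without that library the median was 0.87.

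The extracellular matrix and mucin lists lay in the same direction. The matrix list shares Col1a1, Col1a2, Col3a1, Dcn and Lum with the mesenchymal list, so its result is in part the same genes. Of 45 matrix genes, 34 had a fold change above 0, with a median log2 fold change of 0.56. In edgeR 0 passed over all genes, 14 passed when adjusted over the list alone and 19 had an unadjusted p under 0.05. Of the 38 members with an adjusted p in DESeq2, it called 6, all higher (Bgn, Ccdc80, Col5a2, Col6a1, Dcn and Nid2, with a Fisher's exact test adjusted p = 0.000577). That excess was lost without ST14low replicate 3 or 4 (adjusted p = 0.33 and 0.0898). Fn1 (fibronectin) was at 1773 ± 276 CPM in ST14high and 2078 ± 215 CPM in ST14low, and Agrn (agrin) at 1543 ± 218 and 1321 ± 23.6 CPM. Of 15 genes of mucins, trefoil factors and other mucosal secretions, 14 had a fold change above 0, with a median of 0.94. In edgeR 0 passed over all genes, 4 when adjusted over the list alone and 6 at an unadjusted p under 0.05. Of the 12 members with an adjusted p in DESeq2, it called 1, the protease inhibitor Slpi. Slpi was not called without ST14high replicate 3 or without ST14low replicate 1, 2 or 4. Muc1, a membrane mucin, was at 626 ± 384 CPM in ST14high and 341 ± 93.6 CPM in ST14low, and Pigr, the receptor that carries immunoglobulins across epithelia, at 1252 ± 549 and 933 ± 157 CPM. Camera called both lists (adjusted p = 0.003 for the matrix and 0.0029 for the mucins), and neither with an estimated correlation (adjusted p = 0.957 with an estimated correlation for each). Both lists were highest in ST14high replicate 1, and without it the medians were 0.14 for the matrix and 0.49 for the mucins. Without ST14high replicate 3 or 4 the mucin median was 1.5 or 1.45.

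Most tested genes of the macrophage, lymphocyte and MHC class II lists had lower values in ST14high. Of 18 macrophage and dendritic cell genes 16 had a fold change below 0, and of 15 lymphocyte and pan-leukocyte genes 14. In edgeR 0 of either list passed over all genes. Adjusted over the list alone, 0 macrophage genes and 1 lymphocyte gene passed, 2 and 1 had an unadjusted p under 0.05, and DESeq2 called 0 and 1. The lymphocyte gene was Gzma, a granule protease, at 0.0415 ± 0.0596 CPM in ST14high and 0.863 ± 0.270 CPM in ST14low, called by DESeq2 also without ST14high replicate 1 or 3 and in no other fit with 1 library left out. Without ST14high replicate 1 DESeq2 called 4 lymphocyte and 2 macrophage genes lower, and 4 macrophage genes lower without ST14high replicate 3 (Fisher's exact test, adjusted p = 0.00259, 0.277 and 0.0203). Csf1r, the receptor of a macrophage growth factor, was at 202 ± 30.7 CPM in ST14high and 239 ± 50.7 CPM in ST14low, Cd14, a receptor for bacterial lipopolysaccharide, at 84.5 ± 10.4 and 89.9 ± 20.9 CPM, and Laptm5, a lysosomal protein of leukocytes, at 7.49 ± 6.97 and 16.0 ± 8.90 CPM. Of the genes of resident liver macrophages, chosen here after their values were seen, Clec4f was at 20.6 ± 19.1 CPM in ST14high and 102 ± 64.5 CPM in ST14low and Cd5l at 18.7 ± 18.2 and 85.2 ± 55.5 CPM, with 46.5 and 43.6 CPM in ST14high replicate 1. All 9 tested MHC class II genes had a fold change below 0, with a median of -0.97; 0 passed over all genes or adjusted over the list alone in edgeR, 2 had an unadjusted p under 0.05, and DESeq2 called 0, or 3 without ST14high replicate 2 and 1 without ST14high replicate 3, all lower. Cd74, the invariant chain of MHC class II, was at 109 ± 42.4 CPM in ST14high and 179 ± 87.3 CPM in ST14low, and H2-Ab1 at 35.8 ± 22.9 and 70.2 ± 37.2 CPM. Camera called the 3 lists (adjusted p = 6.46e-09 for macrophages, 8.72e-08 for lymphocytes and 0.000135 for MHC class II), and none with an estimated correlation (adjusted p = 0.917 with an estimated correlation for each). List means separated the populations for MHC class II (exact permutation p = 0.0286) and not for macrophages or lymphocytes (exact permutation p = 0.0857 and 0.0571). Without ST14low replicate 3 the MHC class II median was -0.58, and without ST14high replicate 1 the lymphocyte median was -2.21. ST14high replicate 3 held the lowest mean of all 3 lists.

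Endothelial, hepatocyte and ribosomal protein genes lay lower in ST14high by less. Of 21 endothelial genes 19 had a fold change below 0, with a median of -0.51. Ptprb, a phosphatase of endothelium, was at 137 ± 171 CPM in ST14high and 175 ± 142 CPM in ST14low, and Eng (endoglin) at 76.0 ± 94.9 and 83.3 ± 48.4 CPM. They were at 387 and 215 CPM in ST14high replicate 1, and their log2 fold changes of -0.35 and -0.13 were -1.70 and -1.49 without it, and 0.03 and 0.25 without ST14high replicate 3. Without ST14high replicate 1, 2 or 3 the endothelial median was -1.62, -0.25 or -0.22, and without ST14low replicate 3 or 4 it was -0.27 or -0.79. Camera called the list (adjusted p = 3.33e-05), and did not without ST14high replicate 3 (adjusted p = 0.339). All 30 hepatocyte genes had a fold change below 0, with a median of -0.45 (camera adjusted p = 0.000113). Alb (albumin) was at 7556 ± 2866 CPM in ST14high and 8240 ± 2390 CPM in ST14low, and Ahsg (fetuin-A) at 710.4 ± 277 and 953 ± 108 CPM. The hepatocyte median was -0.30 without ST14high replicate 1, -0.85 without ST14high replicate 4, -0.24 without ST14low replicate 2 and -0.68 without ST14low replicate 4. Of 32 genes of the cytosolic ribosome 24 had a fold change below 0, with a median of -0.17 (camera adjusted p = 0.034). Rpl4 was at 587 ± 72.4 CPM in ST14high and 545 ± 77.7 CPM in ST14low, and Rps3 at 385 ± 16.5 and 446 ± 130.3 CPM. Without ST14low replicate 2 the ribosome median was 0.04 (camera adjusted p = 0.738), and the call was also lost without ST14high replicate 2 or 3 (adjusted p = 0.0913 and 0.0837). In edgeR 0 genes of the 3 lists passed over all genes or adjusted over the list alone, 1, 2 and 1 had an unadjusted p under 0.05, and DESeq2 called 0. For each the adjusted p was 0.957 with an estimated correlation. List means did not separate the populations (exact permutation p = 0.457 for endothelium, 0.2 for hepatocytes and 0.343 for the ribosome).

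**Figure D3:**
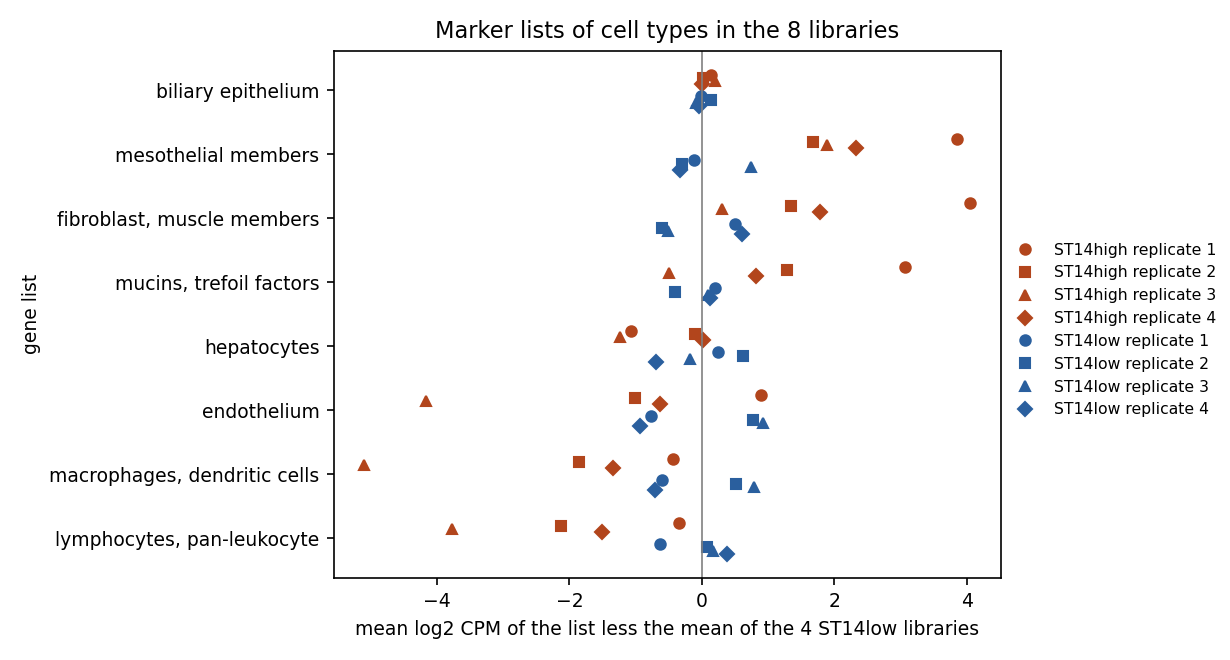
The horizontal axis shows each library's mean log2 CPM over a list's genes less the mean of the 4 ST14low libraries, for the lists on the vertical axis; colours mark the populations and symbols the replicates. All 4 ST14high libraries lie above the ST14low libraries in the 5 mesothelial members of the mesenchymal list, ST14high replicate 1 lies farthest right in the mesothelial, fibroblast and mucin lists, and ST14high replicate 3 lies farthest left in the endothelial, macrophage and lymphocyte lists.

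Camera called none of the lists of duct cell function. The median log2 fold change was 0.16 for bile secretion and ion transport (26 genes, adjusted p = 0.877), -0.03 for apical junctions and polarity (36 genes, adjusted p = 0.83) and 0.03 for the primary cilium (42 genes, adjusted p = 0.37). With 1 library left out these medians crossed 0, to -0.05 for bile secretion without ST14high replicate 1, 0.03 for junctions without ST14low replicate 2 and -0.08 for the cilium without ST14high replicate 3. The cilium list was called higher at the preset correlation without ST14high replicate 1 or ST14low replicate 4 (adjusted p = 0.0162 and 0.0421). The matriptase system, which holds St14 with its activators, inhibitors and substrates, had a median of 0.02 (20 genes, adjusted p = 0.983) and of -0.07 without ST14high replicate 1. Of these 4 lists DESeq2 called 1 gene, Tmprss4, a membrane protease of the matriptase system, at 22.7 ± 33.9 CPM in ST14high and 0.970 ± 0.756 CPM in ST14low, higher with 73.2 CPM in ST14high replicate 1. The populations overlapped, and the call was lost without ST14high replicate 1 or 3 or ST14low replicate 2 or 4. Atp1b1, a sodium pump subunit, was at 1263 ± 95.7 CPM in ST14high and 1131 ± 195 CPM in ST14low, and Slc5a1, a sodium and glucose transporter, at 479 ± 120 and 654 ± 106 CPM. The junction genes Cdh1 (E-cadherin) and Dsg2 (a desmoglein) were at 2045 ± 190 and 2380 ± 315 CPM and at 2660 ± 647 and 2754 ± 413 CPM. Spint2, an inhibitor of matriptase, was at 407 ± 47.2 and 405 ± 57.1 CPM. The ciliary genes Pkhd1 and Pkd2 were at 1555 ± 215 and 1634 ± 305 CPM and at 362 ± 31.7 and 311 ± 66.2 CPM.

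Camera called none of the signalling and proliferation lists. The medians were 0.02 for Wnt and Lgr5 stem cell genes (25 genes, adjusted p = 0.827), -0.04 for the Notch pathway (22 genes, adjusted p = 0.522) and 0.02 for YAP targets (26 genes, adjusted p = 0.792). They were 0.002 for the cell cycle (38 genes, adjusted p = 0.131), -0.002 for epithelial growth factor signals (37 genes, adjusted p = 0.37) and 0.01 for integrins and focal adhesion (29 genes, adjusted p = 0.37). Except for the Wnt list they crossed 0 with 1 library left out, to 0.06 for Notch and 0.05 for growth factors without ST14low replicate 3, -0.07 for YAP targets without ST14low replicate 2, -0.03 for integrins without ST14high replicate 1 and -0.18 for the cell cycle without ST14high replicate 4. The cell cycle list was called lower at the preset correlation without ST14high replicate 4 or ST14low replicate 3 (adjusted p = 0.00038 and 0.00907). Hes1, a Notch target, was at 591 ± 83.6 CPM in ST14high and 847 ± 205 CPM in ST14low (adjusted p = 0.481), and Notch2 at 617 ± 27.3 and 696 ± 145 CPM. DESeq2 called Notch3 higher, at 23.6 ± 29.1 CPM in ST14high and 2.52 ± 0.750 CPM in ST14low, with 66.7 CPM in ST14high replicate 1 and a call also without each library. Acta2 and Des of the mesenchymal list were likewise higher and were highest in that library, at 241 and 57.8 CPM. Whether Notch3 came from duct cells was not tested. Cyr61, a YAP target, was at 2064 ± 198 CPM in ST14high and 3503 ± 1429 CPM in ST14low. All ST14low libraries lay above all ST14high libraries (log2 fold change -0.76, SE 0.26, adjusted p = 0.398 in edgeR). ST14low replicate 2 was highest, at 5510 CPM against 2446 to 3541 CPM in the other ST14low libraries. DESeq2 called Cyr61 lower only without ST14low replicate 3 or 4. Wwc1 was at 588 ± 51.2 and 569 ± 50.4 CPM. Ccnd1 (cyclin D1) was at 921 ± 52.6 and 911 ± 228 CPM, Prom1 at 484 ± 70.8 and 487 ± 103 CPM, and the replication genes Mcm6 and Pcna at 74.4 ± 9.2 and 87.2 ± 18.3 CPM and at 45.8 ± 7.90 and 42.9 ± 10.5 CPM. Of the growth factor list 5 genes passed when adjusted over the list alone, and DESeq2 called 5 (Bmp4, Fgf1, Igfbp5 and Vegfa higher, Id3 lower; Fisher's exact test, adjusted p = 0.00364, and at most 0.0332 with 1 library left out). Camera with an estimated correlation gave an adjusted p of 0.957 and fry 0.844. Bmp4, Fgf1 and Igfbp5 were highest in ST14high replicate 1, Igfbp5 at 1929 CPM against 253 to 462 CPM in the other ST14high libraries. Msln, Wt1 and Dcn of the mesenchymal list were also highest in that library. Whether Bmp4, Fgf1 and Igfbp5 came from duct cells or shared the source of that list's difference was not tested. Fgfr3 was at 1738 ± 381 and 1686 ± 36.7 CPM, Id2 at 876 ± 268 and 1051 ± 46.7 CPM, Tns1 (tensin) at 3004 ± 493 and 3284 ± 653 CPM and Flna (filamin) at 1146 ± 149 and 1136 ± 195 CPM.

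The lists of stress, immune response and metabolism were not called either. The medians were 0.23 for immediate early and stress genes (37 genes, adjusted p = 0.983), 0.32 for NF-kB targets and chemokines (32 genes, adjusted p = 0.792) and -0.12 for the interferon response (30 genes, adjusted p = 0.675). They were -0.19 for cholesterol and lipid synthesis (28 genes, adjusted p = 0.151), -0.11 for oxidative phosphorylation (41 genes, adjusted p = 0.283), 0.17 for glycolysis and the hypoxia response (27 genes, adjusted p = 0.37) and -0.21 for erythroid cells, neutrophils and platelets (6 genes, adjusted p = 0.385). These medians also crossed 0. Without ST14high replicate 1 they were -0.24 for immediate early genes, -0.10 for NF-kB targets and -0.06 for glycolysis. Without ST14low replicate 2 they were 0.03 for the interferon response, 0.10 for lipid synthesis and 0.08 for oxidative phosphorylation, and the erythroid median was 0.15 without ST14high replicate 3. Leaving out 1 library gave calls in 4 of these lists at the preset correlation. With all libraries and an estimated correlation, camera's adjusted p was 0.992 for immediate early genes. It was 0.957 for lipid synthesis, oxidative phosphorylation and glycolysis. Without ST14high replicate 1, immediate early genes and lipid synthesis were called lower (adjusted p = 0.000848 and 0.00937), and lipid synthesis also without ST14low replicate 4 (adjusted p = 0.000814). Oxidative phosphorylation was called lower without ST14low replicate 1 or 3 (adjusted p = 0.0435 and 0.00433) and higher without ST14low replicate 2 (adjusted p = 0.0493). Glycolysis was called higher without ST14low replicate 2 (adjusted p = 0.0493).

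In these lists DESeq2 called Nr4a2, Ptgs2 and Vegfa, all higher, of which only Vegfa was called without each library. Among members, Vegfa, a growth factor for vessels (chromosome 17, 46153943 to 46169326), was at 866 ± 72.6 CPM in ST14high and 544 ± 51.6 CPM in ST14low, a log2 fold change of 0.67 (SE 0.13). Its adjusted p was 0.192 in edgeR and 3.03e-05 in DESeq2, and all 4 ST14high libraries lay above the ST14low libraries. Egr1, an immediate early gene, was at 5780 ± 789 CPM in ST14high and 5535 ± 621 CPM in ST14low, and Jun at 3064 ± 463 and 3905 ± 859 CPM. The complement gene C3 was at 3846 ± 883 and 3358 ± 491 CPM and Nfkbia at 304 ± 151 and 313 ± 56.3 CPM. B2m was at 1185 ± 302 and 1220 ± 97.9 CPM and Irf1 at 259 ± 128 and 207 ± 20.8 CPM. The lipid genes Scd2 and Fasn were at 1122 ± 378 and 1088 ± 367 CPM and at 441 ± 101 and 505 ± 132 CPM, and the ATP synthase genes Atp5b and Atp5a1 at 871 ± 148 and 937 ± 239 CPM and at 791 ± 87.6 and 897 ± 188 CPM. Aldoa, a glycolytic enzyme, was at 416 ± 95.1 and 355 ± 132 CPM, and Alas2, an erythroid enzyme, at 4.46 ± 2.29 and 4.53 ± 2.75 CPM. Ltf (lactoferrin) was at 21.9 ± 28.0 and 1.57 ± 1.40 CPM, with 58.5 and 29.1 CPM in ST14high replicates 1 and 2 and 0 in the other 2.

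Camera called 9 of the 27 lists at the preset correlation, 3 higher and 6 lower in ST14high, and 0 with the correlation estimated from the data. Fry called 0 (smallest adjusted p = 0.534), and the exact permutation test of list means called 0 after adjustment (smallest adjusted p = 0.386). In 7 uncalled lists the median, the mean and camera's direction differed in sign: biliary epithelium, apical junctions, Notch, YAP targets, cell cycle, epithelial growth factor signals, and erythroid cells, neutrophils and platelets.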

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

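The test of exchanged labels and the test of dilution below were chosen after the result was seen. In 84 groups of 4 libraries examined for a library far from the rest, 1 stood out, where about 4.2 (1 in 20) would by chance. St14 in ST14high replicate 3, at 354 CPM, lay above the other ST14high libraries, with a gap of 0.917 of the group's range.

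St14 was not higher in the population sorted for high ST14 (log2 fold change -0.11). Labels exchanged between the groups, for some or all libraries, could hide a 1.5-fold rise only if another division of the 8 libraries showed one; over the 35 divisions, read in either direction, the highest 95% limit of the log2 fold change was 0.55, under the 0.58 of such a rise. This replaced a test on mesothelial genes that could not see an exchange of all labels. Dilution of the ST14high sort by cells without St14 would put St14 above the biliary epithelium list, and the upper 95% limit of its log2 fold change less the median of that list was 0.23, also under 0.58. What stays open, untested here, is that the surface level of ST14 may differ without a difference in transcript, or that the sort divided the cells on another property.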

How the results depend on the processing

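Counts at an unadjusted p, DESeq2 without each library and Fisher's test on its calls, the exact test of list means, the other transcript choices, robust dispersion and the removal of 2 libraries together were chosen after the result was seen, and the splits with DESeq2 after its 234 calls. The count of genes past the adjusted threshold was 0 in edgeR (1315 at an unadjusted p under 0.05, 234 in DESeq2, 0 in voom) and 0 with DESeq2's size factors, upper-quartile factors, either filter, the test against a 1.5-fold change, the longest transcript, summed loci, robust dispersion and each library left out. It was 234 with the DESeq2 Wald test and 1 (Dcn) without ST14high replicate 1 and ST14low replicate 2 together. DESeq2 called 283, 262, 421 and 216 genes without ST14high replicates 1 to 4 and 161, 177, 312 and 163 without ST14low replicates 1 to 4, with 145 to 198 shared with the 234. The cause was not tested. Counts at an unadjusted p ranged from 902 to 1580 with 1 library left out. St14 stayed between -0.21 and -0.005 over 27 alternatives (adjusted p 0.614 to 0.995). With the replicate block edgeR called 2 genes (Myh11 and Acta2). The labels do not say whether equal numbers pair the samples. Deviations of same-numbered libraries correlated at 0.052, 0.052, -0.125 and 0.005 over all genes, which cannot exclude pairing. Within each population, replicate 1 held the highest summed CPM of pancreatic acinar genes (12210 CPM in ST14high and 136.7 CPM in ST14low). The number of lists called by camera was 9, and 7 to 12 with 1 library left out, 9 with the block, 7 with the stricter filter and 7 without both libraries. It was 0 with the estimated correlation, 0 with fry and 0 with the exact permutation of list means. The block ended the endothelial call (adjusted p = 0.0605) and called lipid synthesis (adjusted p = 0.0306), and the stricter filter ended the ribosome call (adjusted p = 0.0767) and left too few lymphocyte genes to test. Without both libraries the matrix (adjusted p = 0.0784), ribosome (0.882) and hepatocyte lists (0.627) were not called, and immediate early genes were called lower (0.002). Of the values of 60 named genes under other settings 659 kept their side of the threshold, and 1, Vegfa, passed only in DESeq2 (log2 fold change 0.661, adjusted p = 3.03e-05). The sign changed in 66 values, none past the threshold. Alternatives planned for normalized values, such as other pseudocounts, were not run since the files hold counts. ST14low replicate 3, the shallowest library, limits genes of low count.

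Over the 35 splits of the 8 libraries into 4 and 4, the count of 0 genes in edgeR was reached by 35 splits (highest other 0), as any split reaches a count of 0, so it cannot exclude chance or speak for it. For genes at an unadjusted p the real split gave 1315 and the highest other 1246, and for DESeq2 234 and 45. In both counts only the real split itself reached its value, a share of 1 of 35. That share is under the 5% rule, but it is the smallest possible and was not adjusted over the counts examined. Both counts were examined after the result was seen, and for the unadjusted count the margin was narrow. Chance is therefore not firmly excluded for either count. For gene lists 32 splits called as many as the real 9, with up to 16, so chance is not excluded.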

Other observations

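Chosen after the result was seen were the tests of a single library and of a lower duct share, the test of expression by duct cells, and the lists of mesothelial members, fibroblast members and pancreatic enzymes; the genes below were chosen after their values were seen. A group of genes with small spread and moderate fold changes lay higher in ST14high in all 4 libraries, none past edgeR's test over all genes. Cttnbp2, a cortactin-binding protein, was at 107 ± 7.29 CPM in ST14high and 63.5 ± 6.84 CPM in ST14low (log2 fold change 0.75, SE 0.12), Echdc2 at 138 ± 17.6 and 76.6 ± 9.52 CPM, Als2cl at 167 ± 16.6 and 104 ± 9.87 CPM, Lrch4 at 65.5 ± 4.88 and 42.1 ± 4.31 CPM and Tle2, a corepressor, at 103 ± 19.5 and 47.6 ± 13.9 CPM. In the other direction lay Bdkrb2, a bradykinin receptor, at 40.1 ± 8.79 CPM in ST14high and 80.0 ± 17.6 CPM in ST14low (SE of the log2 fold change 0.21), Egflam at 142 ± 24.1 and 214 ± 11.2 CPM, the growth factor gene Pdgfc at 288 ± 39.5 and 409 ± 14.6 CPM, and Id3 and Smad6, targets of BMP signals, at 156 ± 17.6 and 225 ± 19.2 CPM and at 51.2 ± 3.89 and 74.1 ± 10.9 CPM. Over 6 further BMP targets the difference in mean log2 CPM was -0.21 (exact permutation p = 0.371), within the spread between libraries.

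The median over the macrophage and lymphocyte genes together was -1.73; it was -1.25 without ST14high replicate 3, -1.45 without ST14low replicate 3, -2.28 without ST14high replicate 1 and -1.63 with libraries thinned to the smallest, while the mesothelial median was 2.333 in the other direction without ST14high replicate 1.

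The mesothelial members of the mesenchymal list lay higher in ST14high, with a median log2 fold change of 3.33, Gpm6a (0.18) being the exception. The tables argue against a single library, ST14high replicate 1, as the whole cause (median 2.333 without it). They also argue against library depth (3.225 with libraries thinned to the smallest). A lower share of duct cells, filled by all other cell types alike, would raise macrophage genes too. Their highest median with 1 library left out was -1.396. That test was written with the macrophage values known, so it gives no separate support. It cannot see a lower duct share filled by mesothelial cells alone. A larger share of mesothelial cells in the ST14high sort may account for it: of 9 further mesothelial genes, listed before they were looked at, 6 were tested, with a median of 2.268 (1.47 without ST14high replicate 1) and populations that did not overlap (exact permutation p = 0.0286). The most abundant of these, Efemp1, was at 405 ± 62.2 CPM in ST14high and 311 ± 23.5 CPM in ST14low, and the gate on MIC1-1C3, which marks duct cells, would act against such cells. Expression of these genes by ST14high duct cells stays open. The difference was not limited to mesothelial genes. All 10 fibroblast and muscle members of the mesenchymal list had a fold change above 0, with a median of 2.33 (1.18 without ST14high replicate 1). Their mean log2 CPM overlapped between the populations (exact permutation p = 0.0857). Whether mesothelial cells alone could account for these members was not tested.

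Pancreatic enzyme genes stood high in ST14high replicate 1, with Ctrb1 (chymotrypsinogen) at 1896 CPM and Cela2a (an elastase) at 1559 CPM. Pancreatic acinar genes summed to 12210 CPM there, 1803 CPM in ST14high replicate 2 and 136.7 CPM in ST14low replicate 1. The tables argue against expression shared by the duct cells of all 4 ST14high libraries, since 2 of these lay at or below the highest ST14low library. That test was written after the enzyme values were seen and restates them, so it gives no separate support. Pancreatic acinar cells or their RNA in that library may be the source: 19 further acinar genes lay 5.309 above the highest ST14low library in mean log2(CPM + 0.5). The bound was written before these genes were looked at, but the score was first taken over the 1 gene that passed the filter (Bhlha15) and was set to the 19 genes with a count after that first result, which also met the bound. How such RNA reached the library stays open, and so does the source of other genes high there, such as Dmbt1 at 23974 CPM against 1250.3, 1.09 and 391 CPM in ST14high replicates 2 to 4.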
